A study of Caenorhabditis elegans with 2 samples.

How the data were processed

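The series holds transcription factor ChIP-seq of 2 biological replicate libraries, both from whole L4 larvae of strain RW12275 at 48 h, and per the labels the chromatin was sonicated to a size range of 200 to 800 bp. The labels name ce11 as the genome build; the aligner, the peak caller and their versions are not given in the sources used here. The files used are peak lists of the authors, 2 for each replicate and 4 for the series. For each replicate there is a ranked list of candidate peaks and a thresholded list. Per the descriptions deposited with them by the authors, each list derives from the alignments and 1 input file shared by both libraries, and the thresholded lists also from a further file whose role is not stated.

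The score of each peak, as deposited by the authors, follows the irreproducible discovery rate (IDR), a measure of how well the rank of a peak repeats between paired peak lists. In the ranked lists it equals the transformed global IDR to within 1, and the lowest score in each thresholded list is 830, which corresponds to a global IDR of about 0.0100. The signal of each peak is the value that the authors' peak caller gave it in the deposited lists; its scale is not stated and it is used only within a list. The −log10 of the global IDR is a column of the ranked lists the authors deposited, and was used here to check the score.

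The larger of the series' thresholded lists, the optimal list, was the main list, and the other the conservative list. The conservative list is contained in a ranked list whose paired peaks are those of replicates 1 and 2; the paired peaks of the ranked list behind the main list are of neither replicate list, and what they are is not stated in the sources used here. The position of a peak is its summit. Genes came from the Ensembl release 115 annotation of WBcel235, the same assembly as ce11, and tRNA products from the RefSeq annotation, which gave a product for 607 of 612 tRNA genes. All coordinates are 1-based. The mitochondrial genome was left out.

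A promoter window ran from 1000 bp upstream to 300 bp downstream of an annotated protein-coding start, and a gene was called bound when a main-list summit lay in it, with no statement on regulation. A noncoding gene was called bound when a summit lay within 500 bp of its start. Summit classes were set in the order promoter, 5′ UTR, coding exon, 3′ UTR, intron and intergenic. Overlaps and classes were tested against 10000 random placements within chromosomes. Gene lists and biotypes were tested with the two-sided Fisher exact test and Benjamini-Hochberg adjustment over 34 lists and over 8 biotypes, and summits near each biotype also against 2000 random placements within chromosomes; intervals of odds ratios add 0.5 to each cell. Chromosome shares were tested with a Monte Carlo chi-square of 100000 draws and exact binomial tests, with exact (Clopper-Pearson) intervals that cover counting error only. The outer parts of an autosome, 33.3% of its length at each end, were taken as its arms. The 6-mers, collapsed with their reverse complements to 2080, were compared between 101 bp at the summit and 101 bp at a distance of 300 bp on a random side with exact McNemar tests, and GC content with a sign-flip permutation test of 100000 resamples.

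The genes named were Y75B8A.6; the protein-coding genes whose promoter window held the summits of the 25 peaks of highest signal, or else the gene with the nearest start; up to 4 bound members of highest signal of each list with an adjusted p of at most 0.05 or at least 3 bound genes; and up to 3 members of each noncoding biotype past that threshold. This rule, the lists, most tests and most alternatives were fixed before the data were examined. The placement test of summits near each biotype was added later, as were the tests so marked below. The alternatives were other peak lists, promoter windows, placements, overlaps, backgrounds and 6-mer controls, and the list of either replicate alone; those added later are named in the closing section.

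The tests were also run on simulated peaks. In 20 draws of 933 random summits, the promoter test made 0 calls in 20, the list test 0 calls in 680 and the 6-mer test 2 calls in 41600. No count on random summits was kept for the biotype test. The random summits were not matched for GC content, so the 6-mer draws do not cover the GC difference at the real summits. Planted promoter summits, 10 planted proteasome genes among 34 lists, 30 planted tRNA summits among 8 biotypes and 1 planted 6-mer among 2080 were each recovered. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.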

Results

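The data were chromatin immunoprecipitation sequencing (ChIP-seq) peaks of Y75B8A.6, a C. elegans gene known here by its sequence name (WBGene00013543). The animals were of strain RW12275, in which CRISPR had inserted a TY1, enhanced green fluorescent protein (EGFP) and FLAG tag at the gene on chromosome III, and the precipitation used an antibody against the fluorescent protein. Whole L4 larvae, the last larval stage before adulthood, were collected at 48 h after synchronisation of the L1 animals by starvation. The 2 libraries were biological replicates of 1 group, and the question open to the data was where in the genome the tagged protein was found. No second condition was measured, so no difference between conditions was tested. Read depth per library was not used here, because the peak lists carry no read totals, and the precision of each share below rests on numbers of peaks.

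The main list held 933 peaks with a median width of 256 bp, the other thresholded list of the series (the conservative list) held 798, and 606 intervals were identical in both. The thresholded list of replicate 1 alone held 343 peaks and that of replicate 2 held 345. The signal per peak is the value of the authors' peak caller and is used only to describe, rank or filter peaks within a list. In the main list it ran from 2.57 to 302.1, with a median of 61.7.

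Of the 25 strongest peaks, 13 had their summit in a promoter window. The peak of highest signal, 302.1, stood at chromosome III 3867489 to 3867642 (build ce11), in the promoter of rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit. Other promoters among the 25 strongest peaks were those of mog-4 (242.4, II 14561795 to 14561933), which encodes a splicing-related helicase, and cdc-48.1 (238.1, II 10563506 to 10563641), a AAA ATPase of protein turnover. The promoters of rpl-20 and Y17G9B.5 shared 1 summit (178.5, IV 4750023 to 4750140), as did those of rpl-15 and K11H12.8 (176.1, IV 654787 to 655042). The heat shock 70 family genes F44E5.4 and F44E5.5, which are transcribed in opposite directions, shared the peak with a signal of 245.8 at II 11759365 to 11759517.

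Further promoters in this set were those of tasp-1 and K01G5.10 (230.2, III 10759179 to 10759304), rpa-2 (203.4, I 4769597 to 4769660), pck-2 (165.5, I 7869012 to 7869181), sec-61.G and F32D8.13 (163.5, V 10897318 to 10897427), eel-1 (154.2, IV 3050351 to 3050606), K12H4.5 (151.7, III 8043853 to 8044108) and wwp-1 (149.9, I 536827 to 536908). The gene pck-2 encodes a phosphoenolpyruvate carboxykinase, and sec-61.G a subunit of the channel that moves proteins into the endoplasmic reticulum. All 25 of the strongest peaks overlapped a peak of the conservative list and of the thresholded list of each replicate.

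Strong peaks also stood away from protein-coding starts. The second and sixth in rank flanked the same part of chromosome IV. One of them was 150 bp upstream of the noncoding RNA gene K08F11.7 (265.7, IV 4725537 to 4725667, intergenic), and the other upstream of the pseudogene K08F11.6 (237.2, IV 4727979 to 4728102, intergenic). A peak with a signal of 208.1 at IV 15895949 to 15896204 was intergenic, 366 bp downstream of the start of the piRNA gene 21ur-15381. The snoRNA genes ZK994.7 (183.0, V 8500543 to 8500610, intron), T03F7.8 (139.7, V 11314063 to 11314318, intron) and T06C12.16 (134.9, V 15873844 to 15874099, intergenic) had summits 26, 67 and 46 bp upstream of their starts. The 6 others were a summit in a coding exon nearest to the noncoding gene K02F3.13 (165.5, III 835910 to 835988), intronic summits nearest to the starts of mdt-26 (160.4, II 5661728 to 5661810), ccm-2 (152.2, IV 1831267 to 1831522) and epg-9 (139.7, IV 2602037 to 2602292), and intergenic summits nearest to Y54F10AM.8 (152.4, III 2497953 to 2498031) and the pseudogene K07D4.1 (151.5, II 4048032 to 4048098).

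The tagged gene itself had no thresholded peak. Y75B8A.6 lies on the minus strand of chromosome III from 12122738 to 12130343, and within 2000 bp of it none of the 4 thresholded lists held a peak. The ranked list of both libraries held 21 lower-ranked peaks there. The best of them had a signal of 42.4 and stood 2285th of 103934, with a score of at most 385 against the minimum of 830 in the thresholded lists.

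The replicates shared close to equal parts of their peaks. Of the 343 peaks of replicate 1, 165 (48.1%) overlapped a replicate 2 peak by 1 bp or more, and 158 of the 345 peaks of replicate 2 (45.8%) overlapped a replicate 1 peak. Random placement within chromosomes gave 0.195% and 0.194% on average, and the one-sided permutation test gave p = 0.0001 both ways, the smallest that 10000 placements can give. The main list overlapped 300 of the replicate 1 peaks (87.5%) and 317 of the replicate 2 peaks (91.9%). In the reverse direction, 286 of the 933 main-list peaks (30.7%) overlapped a thresholded peak of replicate 1, and 319 (34.2%) one of replicate 2. Across the 908 main peaks with a ranked peak in both replicates, the signals had a Spearman correlation of 0.325 and a Pearson correlation of 0.614. Both are across peaks, which are not replicates. Among the 100 main-list peaks of highest signal the Spearman correlation was 0.242. Both sets were selected, by score or by signal, which narrows the range of the values compared. Neither correlation therefore measures agreement over all candidate peaks.

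**Figure D1:**
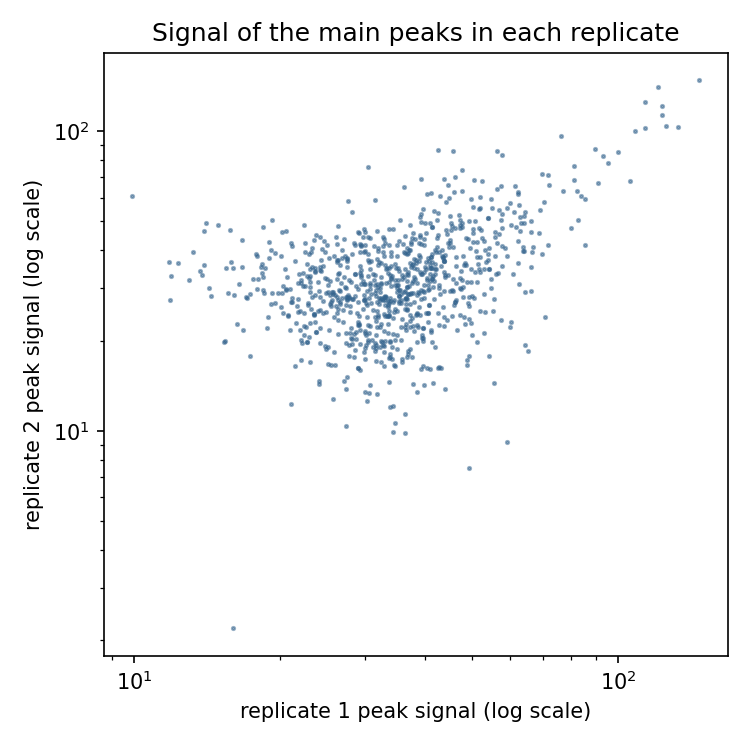
Signal of the main-list peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log scales in the units of the authors' peak caller; each point is 1 of 908 peaks. The points form a broad cloud, with a Spearman correlation of 0.325 across peaks.

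Genes for tRNA, snoRNA and snRNA were bound more often than other genes. Of 612 annotated tRNA genes, 191 (31.2%) had a summit within 500 bp of their start, against 1.47% of all other genes, an odds ratio of 30.3 (95% interval 25.18 to 36.6), which was 18.3 without replicate 2. Of 346 snoRNA genes, which guide the modification of other RNAs, 55 (15.9%) were bound, with an odds ratio of 10.6 (7.92 to 14.3), and 14 of the annotated snRNA genes (10.9%) were bound, with an odds ratio of 6.51 (3.87 to 11.6). In the other direction, 27 of 15363 piRNA genes (0.176%, odds ratio 0.0638) and 9 of 2128 pseudogenes (0.423%, odds ratio 0.216) were bound. The pseudogene odds ratio was 0.105 without replicate 1 and 0.134 without replicate 2. Two-sided Fisher exact tests adjusted over the 8 biotypes gave p = 5.11e-179 for tRNA, 8.22e-34 for snoRNA, 1.95e-07 for snRNA, 5.43e-109 for piRNA genes and 8.32e-09 for pseudogenes. These tests take each gene as a separate unit, although neighbouring genes share summits. For every other biotype the other genes include the 15363 rarely bound piRNA genes, which lowers the share it is set against. A background without piRNA genes was not tested. Counted by summit, 18 lay near piRNA starts, where random placement gave 42.7 on average, and 8 near pseudogene starts, against 17.7. A permutation test of these counts, added after the data were seen, gave an adjusted two-sided p of 0.00160 for piRNA genes, which rests on the smallest p that 2000 placements can give, and 0.0103 for pseudogenes.

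The tRNA summits lay close to the genes. There were 169 such summits, 18.1% of the list, where random placement gave 5.24 on average and 13 at most in 2000 draws. Their median distance to the nearest tRNA start was 22 bp, and 165 of the 169 were within 100 bp. The strongest stood at M02F4.t1 and M02F4.t2, genes for glycine and glutamate tRNAs that shared the peak at X 3036058 to 3036313 (132.2, intergenic), and at F41D9.t3, an asparagine tRNA gene in an intron (130.8, X 8404380 to 8404635).

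Among the snRNA genes the strongest peaks were at R07E5.16 (123.4, III 10989554 to 10989809, intron), the spliced leader gene sls-2.4 (114.7, I 4172133 to 4172388, promoter) and F54D8.7 (113.5, III 5080759 to 5081014, promoter). The class of other noncoding RNA genes had 244 of 7764 bound (3.14%, odds ratio 1.99), with an adjusted two-sided Fisher exact p of 3.65e-17, but 156 of these 244 took their summit from one that was also within 500 bp of a tRNA, snoRNA or snRNA start. The genes it was set against (1.61% bound) also include the rarely bound piRNA genes, which raises this odds ratio. Its strongest members were K08F11.7, Y65B4BR.10 (149.9, in the wwp-1 promoter) and T03F7.14, which shares the peak of T03F7.8. The strongest bound piRNA genes were 21ur-15381, 21ur-12279 (134.5, I 12652156 to 12652411, in the atp-1 promoter) and 21ur-14981 (93.1, I 7656690 to 7656945, promoter). The pseudogenes were K08F11.6, Y94H6A.t1 (73.9, IV 2740096 to 2740351, intergenic) and Y53G8B.3 (71.6, III 3112041 to 3112296, intergenic). The summit given to Y53G8B.3 lay 341 bp from its start and nearer, at 46 bp, to that of another pseudogene, Y53G8B.t9. For miRNA genes 9 of 261 were bound and for lincRNA genes 3 of 194, and the adjusted two-sided Fisher exact tests gave p = 0.0735 and 1. Counted by summit, 8 lay near miRNA starts against 2.24 at random, which passed the permutation test of placements (adjusted p = 0.00533).

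**Figure D2:**
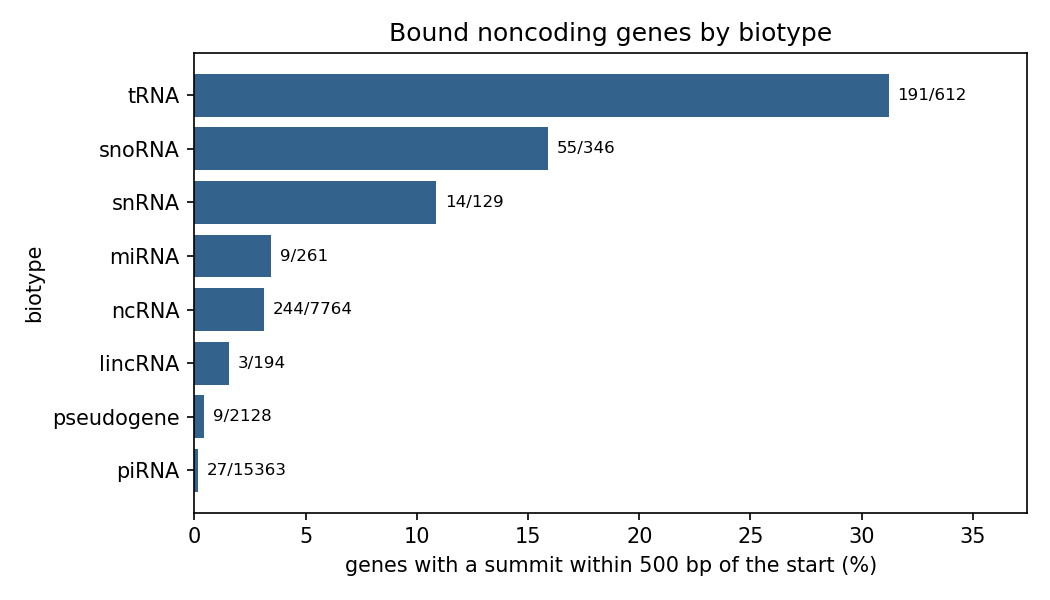
Percent of annotated genes with a main-list summit within 500 bp of the gene start, by noncoding biotype; the label beside each bar gives bound genes over all genes. The tRNA bar reaches 31.2%, and the piRNA bar is the shortest at 0.176%.

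Summits were enriched in the promoters of protein-coding genes and depleted in their coding exons. Of the 933 summits, 385 (41.3%) lay in a promoter window, from 1000 bp upstream to 300 bp downstream of a start, against 27.6% ± 1.45 (SD over placements) at random. Coding exons held 7.07% against 17.9%, and introns 20.6% against 26.8%. The one-sided permutation test of the promoter share gave p = 0.0001, the smallest 10000 placements can give, and the two-sided tests of these 3 classes gave an adjusted permutation p of 0.0004, which rests on the smallest p the placements can give. Intergenic sequence held 27.9% against 24.99% (adjusted two-sided permutation p = 0.0705), 3′ UTRs 3.00% against 2.37% (p = 0.313 in the same permutation test) and 5′ UTRs 0.214% against 0.338% (p = 0.779 in that permutation test). The intergenic share did pass with the conservative list (28.2%), the peaks of higher signal (30.8%), without replicate 1 (31.6%), with the peaks shared with the conservative list (29.9%) and with left-out peaks added (35.2%; adjusted permutation p of 0.0003 to 0.0408). The 3′ UTR share passed without the tRNA summits (3.66%, adjusted permutation p = 0.0384).

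**Figure D3:**
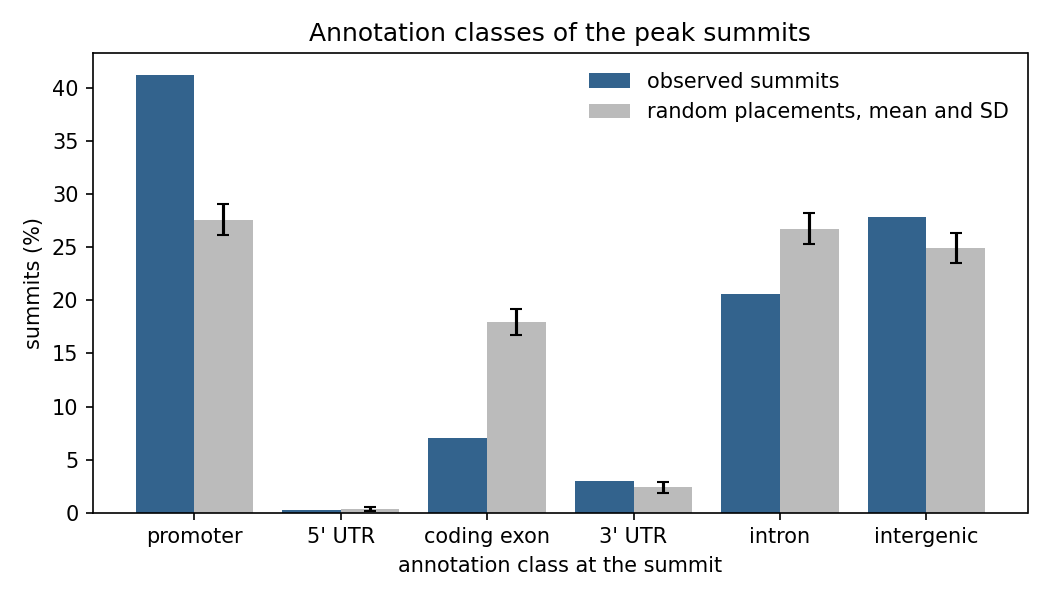
Percent of the 933 main-list summits in each annotation class (blue) beside the mean and SD of 10000 random placements within chromosomes (grey). Promoters hold 41.3% of summits against 27.6% at random, and coding exons 7.07% against 17.9%.

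The promoter summits fell in the windows of 463 of 19973 protein-coding genes (2.32%), and 92 of the 385 summits lay in the windows of more than 1 gene. Bound genes numbered 189 without replicate 1, 177 without replicate 2, 267 with the peaks of higher signal and 296 with a window of 500 bp upstream to 100 bp downstream. Of the 34 lists, 5 were bound more often than other genes and 1 less often. Ribosomal protein genes had 17 of 78 bound (21.8% against 2.24% of other genes, odds ratio 12.2, 95% interval 7.23 to 21.3), among them rpl-3, rpl-20, rpl-15 and rpl-12 (126.9, IV 13240639 to 13240720, promoter shared with lin-54). Of the chaperone and heat shock genes, a list matched by symbol that leaves out F44E5.4 and F44E5.5, 10 of 66 were bound (15.2%, odds ratio 7.67, 4.10 to 15.5), with the highest signals at cct-8 (110.1, IV 1094224 to 1094479), dnj-13 (96.9, II 11545347 to 11545602), hsp-1 (95.2, IV 17278475 to 17278730) and dnj-28 (83.0, I 2996248 to 2996503). Of the mitochondrial respiratory chain and ATP synthase genes, 7 of 43 were bound (16.3%, odds ratio 8.30, 3.97 to 19.3), led by atp-1 (134.5, I 12652156 to 12652411), cox-6A (113.5, III 5080759 to 5081014), cox-5A (111.1, III 12905074 to 12905329) and cox-5B (91.5, I 9788548 to 9788803). The cox-6A summit is also the one assigned to the snRNA gene F54D8.7.

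Translation factor genes had 5 of 41 bound (12.2%, odds ratio 5.91, 2.60 to 15.8), with iff-2 (122.5, II 8561312 to 8561567), ifet-1 (98.3, III 4475529 to 4475784, shared with rps-1), eef-1G (74.99, V 10965565 to 10965820) and eef-1A.2 (63.5, X 7823132 to 7823387) highest. Chromatin regulator genes had 9 of 43 bound (20.9%, odds ratio 11.4, 5.72 to 24.3), led by lin-54, set-16 (124.4, III 13643613 to 13643868), cbp-1 (118.6, III 9765470 to 9765725) and jmjd-1.2 (82.2, IV 4660372 to 4660627). Chemoreceptor genes were bound less often than others, 8 of 1371 (0.584% against 2.45%, odds ratio 0.234, 0.126 to 0.491). The 4 strongest were srh-269 (108.2, V 16592217 to 16592472), sre-23 (105.0, I 8259426 to 8259681), srh-70 (91.6, II 12518890 to 12519145) and srh-2 (87.8, V 731370 to 731625). The first 3 of these summits lay nearer to the start of a tRNA gene (T03E6.t1) or a snoRNA gene (ZK265.10, T21B4.20), and 4 of the 8 were within 500 bp of a tRNA, snoRNA or snRNA start. Two-sided Fisher exact tests adjusted over 34 lists gave p = 7.00e-11 for ribosomal proteins, 2.28e-05 for chaperones, 0.000366 for the respiratory chain, 0.0140 for translation factors, and 5.68e-06 for both chromatin regulators and chemoreceptors. Of the bound members, 13 of 17 ribosomal protein and 7 of 10 chaperone genes shared their summit with another protein-coding gene. So did 4 of 5 translation factor, 7 of 9 chromatin regulator, 2 of 7 respiratory chain and 1 of 8 chemoreceptor genes. With each summit given to its nearest start only, the chromatin regulators no longer passed (odds ratio 3.98, adjusted Fisher exact p = 0.194), and the chaperones passed at an odds ratio of 4.36 (adjusted Fisher exact p = 0.0436). Without replicate 2 the odds ratio was 24.1 for ribosomal proteins, 8.96 for translation factors, 18.7 for chromatin regulators and 0.154 for chemoreceptors, and without replicate 1 it was 14.1 for the respiratory chain. With genes near bound noncoding genes left out of the background, the translation factors did not pass either (odds ratio 5.29, adjusted Fisher exact p = 0.111). No library of animals without the tag was analysed. Signal at strongly transcribed genes without the tagged protein was therefore not separated from these list results.

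None of the lists of cell type markers passed the test in the main list. Of all protein-coding genes 2.32% were bound, and no promoter was bound among the 24 body wall muscle, 19 pharynx, 24 pan-neuronal and 34 germline markers, the 21 molting genes, the 6 furrow collagens or the 85 sperm genes. Intestine markers had 3 of 25 bound (12%, adjusted two-sided Fisher exact p = 0.0741), lec-6 (59.5, III 600656 to 600911), elt-2, the intestinal GATA factor gene (57.2, X 10480671 to 10480926), and fat-6 (54.3, IV 11914965 to 11915220). Hypodermis and seam markers had 1 of 24 bound. Vitellogenin and yolk uptake genes had 2 of 7 bound, with an adjusted two-sided Fisher exact p of 0.0506, and innate immunity effectors 2 of 359, with p = 0.0741 in the same Fisher exact test. These 3 lists passed under some alternatives. Intestine markers did so with the window of 500 bp upstream to 100 bp downstream (odds ratio 9.15, adjusted Fisher exact p = 0.0283), that of 2000 bp upstream to 500 bp downstream (5.42, p = 0.0407) and without the genes near bound noncoding genes (8.66, p = 0.0383). Vitellogenins passed with nearest starts only (21.2, adjusted Fisher exact p = 0.0436) and without tRNA summits (19.03, p = 0.0406). Immunity effectors, bound less often, passed with the 2000 bp window (0.156, adjusted Fisher exact p = 0.00296) and among genes with an approved symbol (0.178, p = 0.0131).

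The remaining lists did not pass. Splicing genes had 4 of 55 bound (adjusted two-sided Fisher exact p = 0.131), snr-4 (71.6, V 11979960 to 11980215), prp-19 (67.9, III 5172537 to 5172792), prp-8 (65.6, III 8163912 to 8164167) and hrpu-1 (55.2, IV 15038840 to 15039095). Nuclear hormone receptor genes had 4 of 269 bound, nhr-255 (70.6, X 15741957 to 15742212), nhr-68 (59.1, V 11572975 to 11573230), nhr-105 (55.98, IV 7049664 to 7049919) and nhr-17 (39.97, X 12668133 to 12668388), and homeobox genes 3 of 93, ceh-99 (91.6, the summit of srh-70), ceh-2 (81.3, I 6051101 to 6051356) and ceh-43 (74.5, III 4450271 to 4450526). All 3 homeobox summits lay nearer to the start of a snoRNA or tRNA gene, as did the snr-4 summit to a snRNA start and the nhr-255 summit to a tRNA start. The promoter windows of 2 genes were bound among 80 histone, 33 proteasome, 74 zinc finger regulator, 185 detoxification and 39 small RNA pathway genes. A single gene was bound among 174 cuticle collagens, 17 heterochronic regulators, 20 vacuolar ATPase, 26 ribosome biogenesis, 31 cell cycle, 40 basic helix-loop-helix, 140 neuropeptide, 40 Wnt, Notch and TGF-beta and 23 insulin signalling genes. For the lists with no p printed, the adjusted two-sided Fisher exact p lay between 0.549 and 1.

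**Figure D4:**
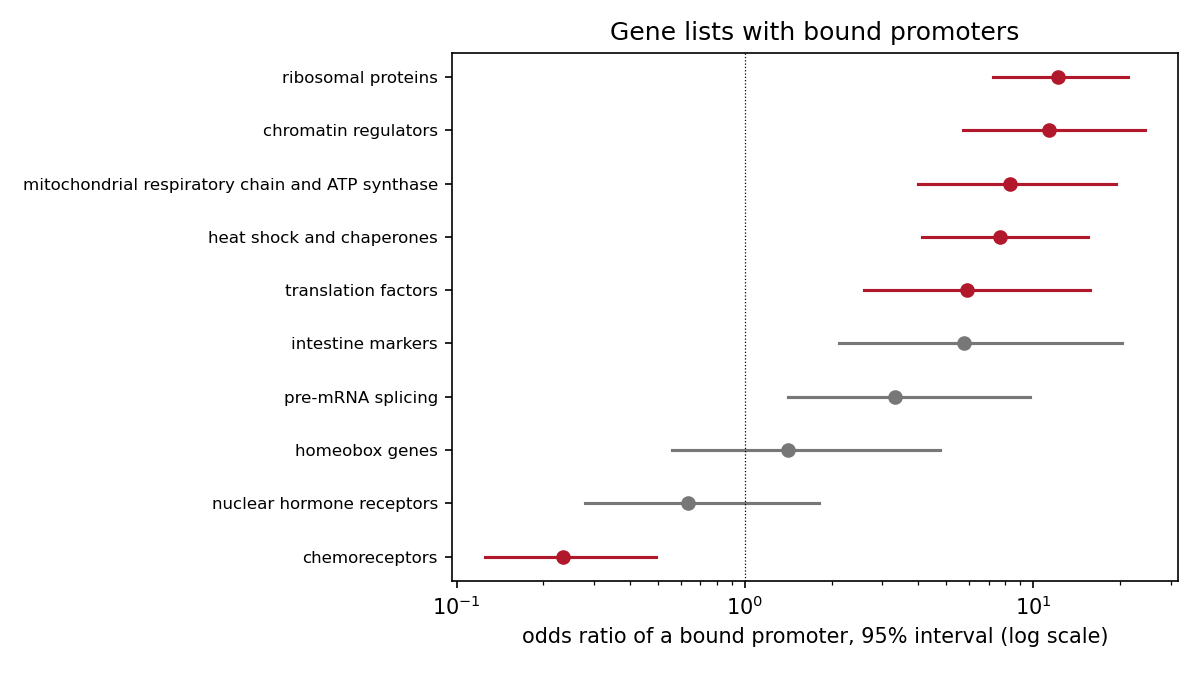
Odds ratio of a bound promoter for each gene list with at least 3 bound genes (points) with its 95% interval (lines), on a log axis; red marks an adjusted p at or below 0.05. Ribosomal proteins stand highest at 12.2 and chemoreceptors lowest at 0.234.

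Chromosome III carried more summits than its length gives and chromosome V fewer. Chromosome III held 162 of 933 (17.4% against 13.7% of length, exact 95% interval 14.99 to 19.9), and V held 143 (15.3% against 20.9%, 13.1 to 17.8). The X chromosome held 187 (20.04% against 17.7%, 17.5 to 22.8), which did not pass the test. Two-sided exact binomial tests adjusted over 6 chromosomes gave p = 0.00589 for III, 0.000113 for V and 0.118 for X, and the Monte Carlo chi-square test of all 6 gave p = 8e-05. Without replicate 1 and without replicate 2, III did not pass (adjusted exact binomial p = 0.0561 and 0.0944), and V did not pass without replicate 2 (0.145), where IV alone did, with 11.95% against 17.4% of length (0.0403). X passed with the peaks of higher signal (22.5%, adjusted exact binomial p = 0.0151). Of the 187 X summits, 93 were tRNA summits. Without the tRNA summits, X held 94 of 764 (12.3%), below its share of length (exact binomial p = 6.47e-05, adjusted 0.000194). On the outer parts of the autosome lengths, the chromosome arms, stood 445 of 746 autosomal summits (59.7%), against 61.9% of gene starts, with a two-sided exact binomial p of 0.214. Against their 66.7% of length the arms held fewer summits (exact binomial p = 6.19e-05).

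Summit sequences were richer in G and C than their flanks. The windows centred on summits held 46.3% ± 9.04 (SD over 933 peaks) GC and the flanks at 300 bp held 35.3% ± 8.91, a paired difference of 11.0 percentage points ± 0.402 (SE), with a two-sided permutation p of 1e-05, the smallest 100000 resamples can give. Of all 6-mers, 672 differed between summit and flank at an adjusted p of 0.05 in an exact McNemar test, 424 more frequent at summits and 248 less frequent, and 241 differed without replicate 1 and 236 without replicate 2. The most significant at summits were ACCACT, present in 13.4% of summit windows and 2.14% of flanks, and CGAACC, in 11.7% and 2.47%. ACCACT stood in 44.97% of the 169 tRNA summit windows and in 6.41% of the other 764. AAAAAT was the most significant of those rarer at summits, in 22.7% and 48.9%. Against shuffled summit sequences with the same dinucleotide counts, a control added after the data were seen, 136 6-mers passed, 70 of them higher, and ACCACT stayed the most significant (13.4% and 2.79%). In the 169 tRNA summits, GTTCGA stood in 48.5% of windows and 5.33% of shuffled ones. This 6-mer and CGAACC lie in the sequence of the internal promoter element called box B. These windows were selected for lying near tRNA starts, and box B is part of the tRNA gene. Its presence there therefore says nothing on what the tagged protein recognises. The same selection limits ACCACT in these 169 windows. Its rank over all summits draws on them too, so that rank says nothing on recognition either. Without the tRNA summits 43 6-mers passed against the shuffled control, led among the higher ones by ACCGTA (6.28% and 1.31%).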

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

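The tests of tRNA genes with more than 1 copy, of distance to tRNA starts, of signal without the tagged protein, of the left-out peaks on X and of the flanks of stronger peaks were chosen only after the result was seen. Among the candidate peaks of both libraries, 120 of the 1053 that pass the score minimum are not in the main list, and they were left out of the comparisons. Their highest signal is 2354.7, at X 15810952 to 15811191, against 302.1 in the main list, and 13 of them exceed every main-list peak. On average 86.9% of the 30-base words in these peaks occur more than once in the genome, against 12.6% in the main list and 8.73% in 999 random windows.

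Of the 933 main-list summits, 169 lay within 500 bp of a tRNA start. Reads shared between identical copies would spare the 140 tRNA genes whose sequence occurs once, but 20.7% of these were bound (exact 95% interval 14.3 to 28.4), against 1.47% of other genes. The other genes include the rarely bound piRNA genes, which lowers their share. Of the 472 with more than 1 copy, 34.3% were bound (two-sided Fisher exact p = 0.00250 against the single-copy genes, too small because neighbours share summits), so shared reads may add to the peaks there. A gene counted as single when its exact full sequence occurred once, so near-identical copies were not set apart. A summit at a neighbouring tRNA gene within 500 bp also made it bound. The 20.7% therefore does not exclude shared reads at the single-copy genes. Summits that belonged to genes farther off in the 500 bp window would mostly lie farther away than the median of 22 bp. Genes that start as close as the tRNA gene are not set apart by this distance. Of the 169 summits, 44 also lay in a promoter window. Signal at strongly transcribed genes without the tagged protein could also give such peaks, and it stays open because 0 libraries of animals without the tag were analysed here, and no biological explanation was tested, since the design has 1 group. The same limit holds for the peaks at snoRNA and snRNA genes and at the promoters of the gene lists.

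The X chromosome held 20.04% of summits against 17.7% of length, which did not pass its test, but 22.5% with the peaks of higher signal, which did (adjusted exact binomial p = 0.0151), so whether X holds an excess was not settled. Were tRNA genes the source of an excess, the share without the tRNA summits would lie at the share of length; it was 12.3%, below it, and the share was 19.8% with the left-out peaks added back. No excess was left in the main list once the 93 tRNA summits on X were removed. Removing 93 of the 187 X summits would erase an excess of this size whatever the source of those summits. The removal therefore does not show that a surplus rested on the tRNA summits. What sets the X share of the tRNA genes could not be decided from these values. Nor could the reason for the low X share of the other summits. No biological explanation was tested.

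In the main list, 20 peaks had a signal below 16.8, the median of the ranked list, although they passed the score. In 100% of these 20 the paired interval was also matched to a peak of higher signal, against 0.548% of the other 913, and 95% lay within 500 bp of a stronger thresholded peak, against 1.53%. These peaks may owe their score to the pairing with a stronger neighbour, a candidate explanation that both values fit and that this list cannot separate further. Leaving them out kept the promoter result on its side of the threshold.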

How the results depend on the processing

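The settings that leave out tRNA or low-signal summits, keep shared peaks, add back left-out peaks or shuffle dinucleotides were chosen after seeing the data. Of 244 values under alternatives, 223 kept direction and side of the threshold or stayed within 1.5 times. The promoter share passed under all 12 of its alternatives, each tested against random placements for its own window. It was lowest, 27.2%, with the window of 500 bp upstream to 100 bp downstream. The highest share, 55.7%, came with that of 2000 bp upstream to 500 bp downstream. The tRNA, snoRNA, snRNA, other noncoding RNA and piRNA genes and the pseudogenes passed under all 7 of theirs, with tRNA odds ratios of 18.3 (without replicate 2) to 30.5. The setting without tRNA summits was not among these 7. Whether other noncoding RNA genes pass without the summits that 156 of their 244 bound genes shared with tRNA, snoRNA or snRNA starts was therefore not tested. Nor was it tested whether they pass against a background without piRNA genes. Ribosomal proteins (odds ratios 8.88 to 24.1), chaperones (4.36 to 9.40), the respiratory chain (6.48 to 14.1) and chemoreceptors (0.154 to 0.294) passed under all 14. Without replicate 1 or 2, using 1 library alone, bound genes numbered 177 to 189, 6-mers 236 to 241, and 1 chromosome passed (V without replicate 1, IV without replicate 2); the share of III was 17.8% to 18.3% and no longer passed either way, that of V was 14.2% to 17.2% and failed without replicate 2, and the arm share was 59.9% to 64.2%, above the share of gene starts only without replicate 2. Fewer peaks are tested there. Bound genes fell to 267 with the peaks of higher signal and 296 with the window of 500 bp upstream to 100 bp downstream. The 6-mers past the threshold were 436 without tRNA summits, 392 in 51 bp windows, 329 against promoters of unbound genes and 136 against the shuffled control; higher 6-mers were 63.1% of the main calls and 51.5% of the shuffled-control calls. The X share passed at 22.5% with the peaks of higher signal and turned to 12.3%, below its length, without tRNA summits. The arm share of 59.7% was below the share of length, 66.7%, and passed against it. Translation factors (odds ratio 5.29) and chromatin regulators (3.98) lost their call, and intestine markers, vitellogenins, immunity effectors and the intergenic and 3′ UTR classes gained one, as given above. Where no construction shows it, the cause was not tested. No paired analysis was possible because there is 1 group.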

Other observations

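The bound tRNA genes covered 20 amino acids, and none stood apart after adjustment. The shares were highest for aspartate (14 of 27, 51.9%) and glycine (26 of 55, 47.3%) and lowest among those with at least 1 bound gene for asparagine (3 of 20, 15%), and the smallest adjusted two-sided Fisher exact p over 21 products was 0.195. On X, which holds 276 of the 612 tRNA genes, 107 were bound (38.8%), against 84 of 336 on the autosomes (25%, two-sided Fisher exact p = 0.000316). Neighbouring tRNA genes share summits, so this p is too small, and the comparison was chosen after the tRNA peaks were seen.

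By group, the median signal was 76.5 at the 55 snoRNA summits, 73.9 at 14 snRNA summits, 67.3 at the 169 tRNA summits, 61.5 at the 314 other promoter summits and 57.8 elsewhere. Of the 25 strongest peaks, 3 were at snoRNA and 0 at tRNA genes, and of the 100 strongest, 12 and 14.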
